A study of Drosophila melanogaster with 2 samples.

How the data were processed

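Chromatin immunoprecipitation with sequencing (ChIP-seq) of ORC2, a subunit of the origin recognition complex that marks sites where replication can start, was made from hand-dissected salivary glands of wandering larvae of the third instar of Drosophila melanogaster. The series holds 2 libraries, 1 from OrR (the wild type, per the series design text) and 1 from SuUR (a Suppressor of Underreplication mutant). Both used an antibody against ORC2. Groups were taken from the genotype given in the labels.

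The deposited values are coverage, as whole numbers of overlapping extended reads per base, and they were not scaled to depth. Per the file headers, the tracks come from ELAND extended alignments to dm3, and the submitters' processing notes name the build BDGP5. Each track used here covers chromosome arm 2L alone, and the lowest listed value is 5. The aligner version, read filters and the treatment of duplicate reads are not given in the sources used here. The profile steps recur with the opposite sign 200 bases downstream, so each read was taken to be extended to 200 bases. Bases with coverage under 5 are unlisted, and they were set to 0 in sums. Low coverage is therefore understated, and this lowers sums most where coverage is lowest. For every ratio of domains a lower bound was computed with each unlisted OrR base at 4 and each unlisted SuUR base at 0. No input library was used here, so the surroundings in the same library were the control for enrichment, and read amount and ORC2 binding cannot be separated by an input.

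Summed coverage divided by 200 gave read equivalents. In unbroken listed runs of at least 4000 bases the read ends were solved from the steps, and 1177 of 1177 OrR runs and 827 of 827 SuUR runs gave whole, non-negative reads that add up to the coverage. In these runs 31.8% of OrR reads and 47.1% of SuUR reads repeated an end already seen. Variance over mean of reads per base was 1.78 in OrR and 2.50 in SuUR. Counts of both libraries were divided by the larger value before a ratio interval was set. All intervals are 95% intervals, and those of domain ratios, densities and read shares cover counting error only. That of the median log2 ratio covers the spread over regions, taken as if they were independent. With 1 library per genotype there is no replicate check and no test between genotypes, and rules of size were used.

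Domains were found from log2(SuUR/OrR) of read equivalents plus 0.5 in 10 kb windows, centred on the median window and smoothed by a running median over 9 windows. A domain is a run of at least 5 windows with a smoothed ratio of at least 1.5-fold, and windows with under 20 reads over both libraries were left out. Of 2299 windows, 2270 were used. Ratios of domains have exact conditional (Clopper-Pearson) intervals. Low-density runs within a library are runs of at least 5 windows whose running median is at most 0.6 times the median window. Region-free windows are the 1105 windows outside domains that overlap no region of at least 2-fold enrichment in either library and have at least 5000 listed bases in both.

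ORC2-enriched regions were called within each library from 500-base windows every 100 bases. Read equivalents were set against the larger of the 10 kb background, the 50 kb background and the arm mean by a Poisson upper tail with Benjamini-Hochberg adjustment. Windows needed an adjusted value of at most 0.01 and at least 3-fold enrichment, and were merged within 500 bases. OrR was thinned by binomial draws to 88.0% of its reads, the SuUR depth. Fold values at the union of regions are the highest 500-base window over the 10 kb background, at full depth. Densities have exact Poisson intervals, the median log2 ratio has a binomial interval over regions, and regions or domains were also placed at 1000 random shifts along the arm.

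Most of these rules, the alternatives and the rule for named items were fixed before the data were examined, and some steps had to change. Rules that rest on listed or unlisted bases were set after the tracks were seen. They are the region-free windows, the lower bounds of domain ratios, and the recovery of read ends with the values taken from it. The plan assumed read positions. Collapsing of duplicate positions and the strand rule could not be run on coverage, and all reads were used. Results cover 2L, so shares per chromosome were left out. The gene table at hand is on another assembly than the files, so no gene was placed and the 17 gene lists, the promoter comparison and the SuUR gene were not analysed here. Named items are the domains, the 10 regions of highest fold per library with at least 30 reads, and items singled out by the comparisons, chosen after their values were seen. Positions are 1-based on dm3.

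Alternatives were other window sizes, thresholds, scaling, backgrounds, overlap rules and depth. Alternatives added after the data were examined were unlisted bases at 2 or 4, the local background alone at 2-fold, 3-fold and 4-fold, with and without unlisted bases at 4, each read end counted once, and the regions called in OrR. Folds with each end once were taken at regions whose central 500 bases, and at least 80% of the surrounding 10 kb, lay in recovered runs of both libraries. For equal numbers of ends, OrR reads in those runs were thinned to 60.6%. The steps were tested on simulated tracks with the same extension and listing minimum, with regions called at 3-fold and the arm mean in the background. Simulated reads were Poisson draws, without the excess of repeat reads seen here (variance over mean 1.78 in OrR and 2.50 in SuUR). False calls from such reads were therefore not tested in these tracks. There 3 of 3 low-copy domains were found with 0 in the opposite direction. At the 3-fold threshold 62.3% of 69 sites of 4-fold and 100% of 85 sites of 6-fold were called, and 0 regions were called elsewhere. The simulated domains had sharp edges and the same strong loss of OrR reads, so weak or graded domains were not tested. Regions were called in the simulated SuUR track, which had no low-copy domains, so region calls at low coverage were not tested. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.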

Results

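ORC2 ChIP-seq coverage was compared on chromosome arm 2L between polytene salivary glands of wild-type OrR larvae and of SuUR larvae, with 1 library each. Salivary gland chromosomes are polytene, and parts of them are known to stay underreplicated in the wild type and to replicate further when SuUR is lost. The comparison asks how ORC2 and read amount along the arm differ between the genotypes. The tracks span 22.998 Mb and hold 2633086 read equivalents in OrR and 2316591 in SuUR. Coverage of at least 5 was listed at 85.5% of the span in OrR and 87.2% in SuUR, with medians of 20 and 16 at listed bases. There are no replicates, and all differences below are differences between these 2 libraries.

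Read density was higher in SuUR than in OrR across 11 domains of 2L that together hold 2240 kb, or 9.74% of the span. Pooled over the domains, SuUR density was 3.05-fold that of OrR (95% interval 2.995 to 3.105), and at least 1.85-fold with each unlisted OrR base at 4 and each unlisted SuUR base at 0. In OrR the domains held 21.9% of the coverage of region-free windows of the same library, and in SuUR 71.8%. The median region-free window had a coverage of 16.9 in OrR (SD 6.01 over 1105 windows) and 13.4 in SuUR (SD 4.58). Outside the domains the libraries followed each other closely. There 96.2% of 2049 windows lay within 1.5-fold, the SD of the log2 ratio was 0.33, and Spearman's rho across windows was 0.94. Windows are not independent replicates.

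**Figure D1:**
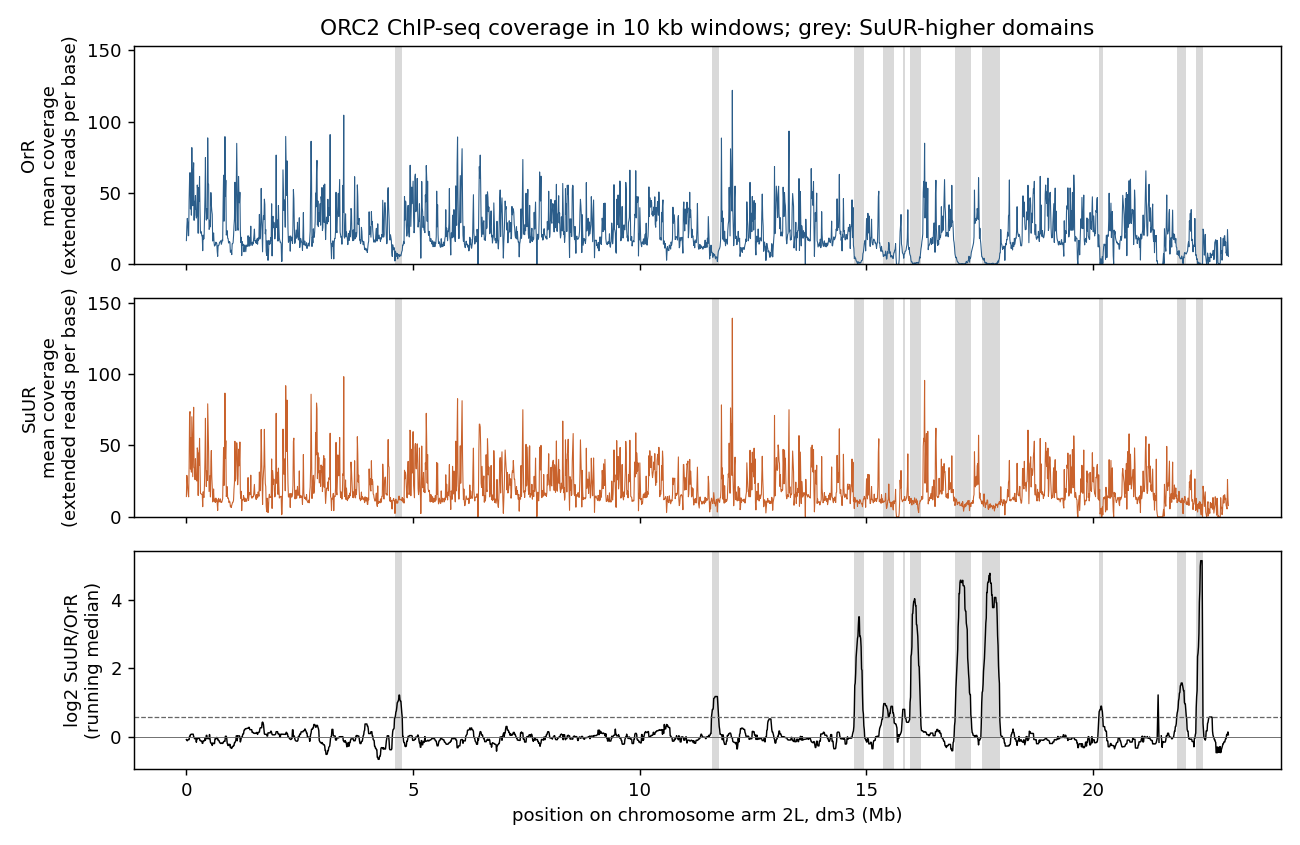
Mean coverage in 10 kb windows along 2L (dm3, position in Mb) in OrR (top) and SuUR (middle), in extended reads per base, and the running median of log2 SuUR/OrR (bottom), with the dashed line at the 1.5-fold threshold. Grey bands are the 11 SuUR-higher domains, where OrR coverage falls and SuUR coverage falls less; the spike near 21.4 Mb borders a stretch with nothing listed and holds under 5 usable windows.

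The largest ratios were found in 5 domains between 4.20-fold and 6.98-fold, 1350 kb in all. The longest domain, 17.54 to 17.94 Mb (400 kb), had the highest ratio with unlisted bases at 0. Its mean coverage was 1.43 in OrR and 8.52 in SuUR, a 6.98-fold difference (6.55 to 7.43). The domain at 16.96 to 17.31 Mb (350 kb) had 1.84 and 8.87, or 5.68-fold (5.35 to 6.03). The domain at 22.27 to 22.42 Mb (150 kb) had a ratio of 5.47 (4.92 to 6.10), that at 15.96 to 16.20 Mb (240 kb) 5.34 (4.99 to 5.72), and that at 14.73 to 14.94 Mb (210 kb) 4.20 (3.94 to 4.49). Between 65.4% and 83.8% of the bases of these 5 domains were unlisted in OrR, so their ratios depend on how low coverage is counted. Their lower bounds were 1.60-fold to 2.29-fold and rank differently, with the highest at 15.96 to 16.20 Mb (2.29), then 14.73 to 14.94 Mb (2.20) and 17.54 to 17.94 Mb (2.15).

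The other 6 domains had ratios of 1.53 to 2.23. They lie at 4.61 to 4.76 Mb (1.99-fold, 1.88 to 2.10), 11.59 to 11.74 Mb (2.09-fold, 1.97 to 2.21), 15.36 to 15.61 Mb (1.70-fold, 1.63 to 1.78) and 15.80 to 15.85 Mb (2.11-fold, 1.92 to 2.32). The domain at 21.85 to 22.06 Mb had a ratio of 2.23 (2.12 to 2.34). The domain at 20.13 to 20.21 Mb had the lowest ratio, 1.53 (1.39 to 1.68). In that domain 62.4% of the bases were unlisted in OrR and 58.7% in SuUR, and its lower bound of 0.998 does not separate the libraries. The lower bound was above 1 in the other 10 domains and at least 1.5 in 9 of them.

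SuUR coverage inside the domains stayed below that of region-free windows. It ranged from 63.8% to 91.3% of that level in 9 domains, where OrR ranged from 8.50% to 43.0%. The 2 domains with 58.7% and 50.5% of bases unlisted in SuUR, at 20.13 and 22.27 Mb, had 45.7% and 48.4% in SuUR. With every unlisted SuUR base of the domain at 4, the domain at 17.54 to 17.94 Mb rose from 63.8% to 71.0% and that at 16.96 to 17.31 Mb from 66.5% to 73.4%. The same change in OrR moved these 2 domains more, from 8.50% to 27.6% and from 10.9% to 29.0%.

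**Figure D2:**
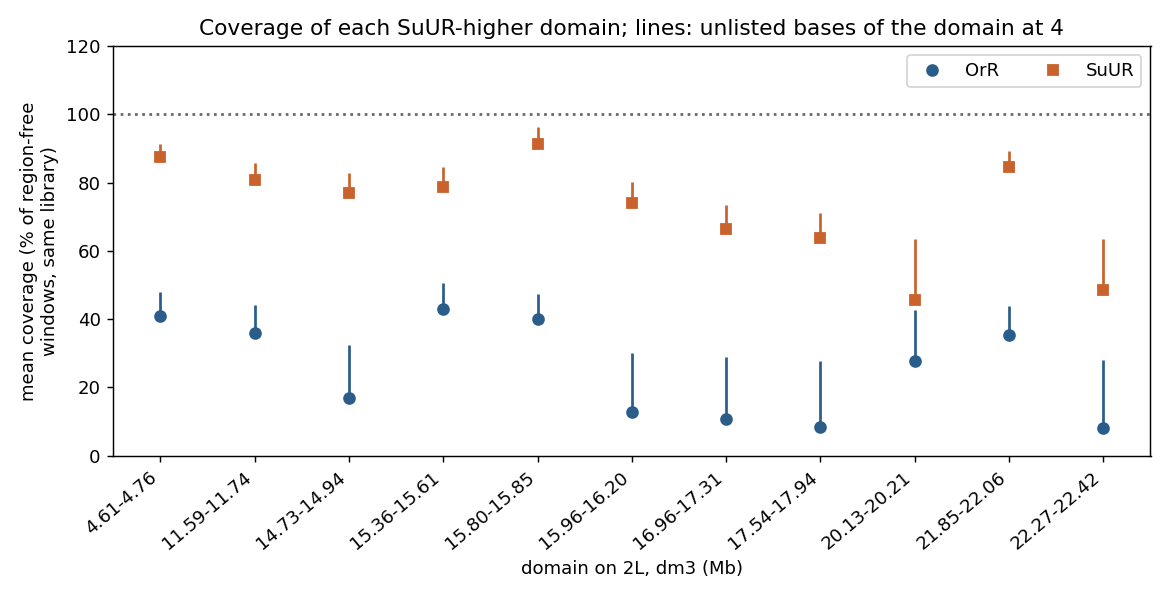
Mean coverage of each SuUR-higher domain (x axis, Mb on dm3) as a percent of the median region-free window of the same library (dotted line at 100), for OrR (circles) and SuUR (squares). Vertical lines reach the value with every unlisted base of the domain at 4; OrR lies at 8.22% to 43.0% and SuUR at 45.7% to 91.3%.

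In the 2 longest domains OrR coverage fell with distance from the domain edges, which were set where the smoothed ratio passes 1.5-fold. It was 26.5% of region-free windows within 30 kb of an edge, 16.2% at 30 to 60 kb, 7.19% at 60 to 90 kb, 4.31% at 90 to 120 kb and 2.58% farther in. Over all domains the OrR values from the edge inward were 35.1%, 23.2%, 17.0%, 17.6% and 4.62%. Those values come from 11, 10, 9, 6 and 3 domains, so the classes differ in the domains they hold. The SuUR values in the 2 longest domains were 73.0%, 71.6%, 69.7%, 61.4% and 58.2%. Each class nearer than 120 kb holds 12 windows and the innermost 27. With unlisted OrR bases at 4, OrR went from 37.7% at the edge to 24.6% in the innermost class, where 93.0% of bases were unlisted.

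**Figure D3:**
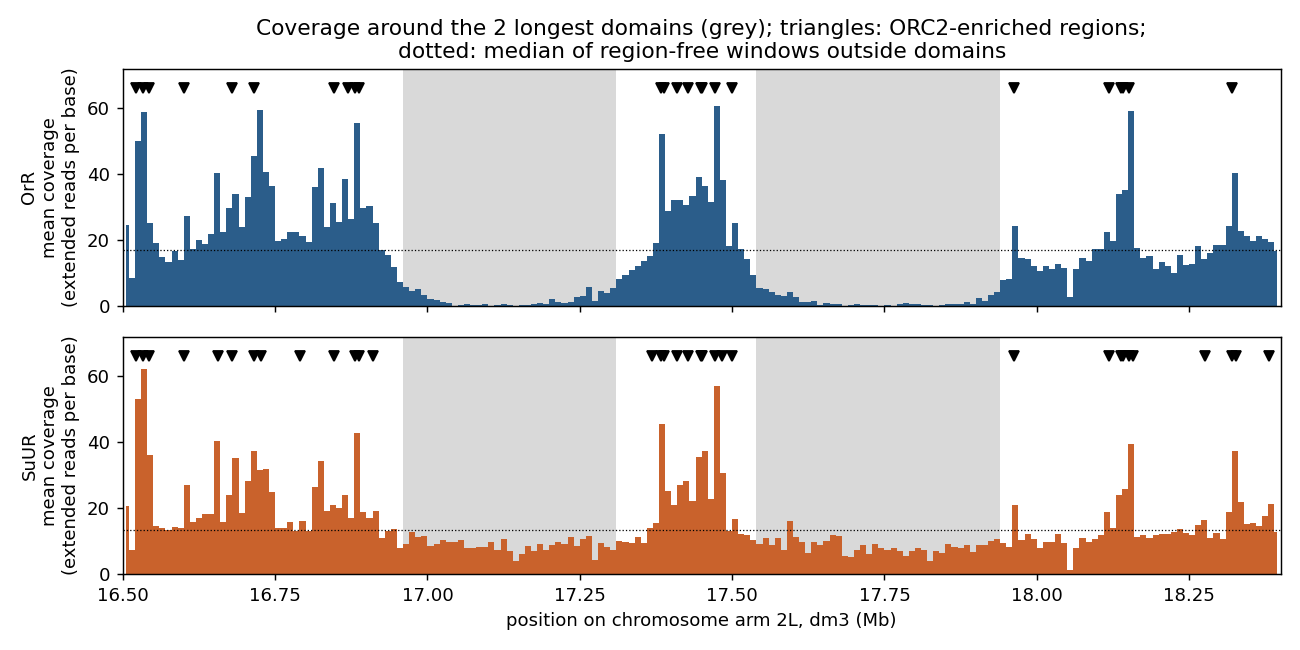
Mean coverage in 10 kb windows (extended reads per base) around the 2 longest domains (grey) in OrR (top) and SuUR (bottom), against position on 2L (dm3, Mb). Triangles mark starts of ORC2-enriched regions and dotted lines the median region-free window (16.9 in OrR, 13.4 in SuUR); OrR coverage declines from both edges toward the middle of each domain.

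Low read density in OrR was also found by a rule that does not use the ratio. The same OrR counts enter the ratio, so overlap of low-density runs with the domains is partly built in. The domains make up 9.74% of the span. In OrR alone 16 low-density runs held 3270 kb, of which 2160 kb (66.1%) lay in SuUR-higher domains, and they touched 10 of the 11 domains. In SuUR alone 5 runs held 1000 kb, of which 550 kb (55%) lay in SuUR-higher domains, and they touched 3 of the 11 domains. There were 6 OrR runs outside the domains. The runs at 12.81 to 12.93 Mb and 3.94 to 4 Mb had SuUR/OrR ratios of 1.38 each, below the domain threshold, and those at 10.59 to 10.65 Mb and 12.22 to 12.29 Mb had 1.25 and 1.23. The runs at 22.47 to 22.69 Mb and 22.75 to 22.85 Mb, at the centromere-proximal end of the arm, had ratios of 1.18 and 0.789, and 47.7% and 76.9% of their bases were unlisted in OrR, against 48.7% and 82.4% in SuUR.

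In the opposite direction 1 domain passed the rule, at 4.21 to 4.26 Mb (50 kb). Its coverage was 20.5 in OrR and 11.8 in SuUR, and the OrR/SuUR ratio was 1.49 (1.38 to 1.60). With unlisted bases at 4 the ratio was 1.44 (1.34 to 1.54) and 3 of its 5 windows kept a smoothed ratio of 1.5-fold, under the 5 required, so 0 domains passed.

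ORC2-enriched regions were more numerous in SuUR at equal total reads, with 552 regions against 368 in OrR. Most OrR regions were also found in SuUR: 342 of 368 (92.9%) overlapped a SuUR region, while 1000 random placements gave a median of 15 and at most 30. Of the SuUR regions 341 (61.8%) overlapped an OrR region. Regions held 13.5% of SuUR reads (13.4 to 13.5) in 483.7 kb and 8.40% of OrR reads (8.34 to 8.45) in 310.8 kb. The median region length was 900 bases in SuUR and 800 in OrR. The counts moved by over 1.5 times with the fold threshold, to 995 and 820 at 2-fold and to 270 and 171 at 4-fold, with more regions in SuUR each time. Repeat reads were 47.1% in SuUR and 31.8% in OrR, so equal totals are not equal numbers of distinct ends. In the 27.0% of the arm where ends were recovered in both libraries, each end counted once at equal numbers of ends gave 120 regions of at least 3-fold in SuUR and 69 in OrR, against 185 and 119 with all reads at equal totals.

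The strongest regions were largely common to both genotypes. Of the 10 regions with the highest fold in each library, 6 were in both lists, all 10 of each list were called in the other library, and 0 lay in a domain. These ranks used the larger background with the arm mean, which lowers folds where coverage is low. Over the 10 kb background the SuUR region at 4660601 to 4661600, inside a domain, had 9.85 in SuUR and 5.31 in OrR. It was not called in OrR with the arm mean in the background. Its SuUR fold of 9.85 is above the 9.83 of the region at 20120501 to 20121600 in the SuUR list. The top region in both, at 21396901 to 21398000, had a fold over 10 kb background of 13.7 in OrR and 14.5 in SuUR. It lies near the longest stretch with nothing listed in either library, 21427102 to 21539441, so reads from repeated sequence could not be excluded there. The region at 14011201 to 14012200 had 10.2 and 12.9, and that at 14705901 to 14706900 had 9.39 and 11.4. The region at 552001 to 553100 was among the top 10 in SuUR alone, with 12.4 against 7.81 in OrR.

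Over the union of 577 regions the median fold was 3.37 in OrR and 4.08 in SuUR, and the median log2 ratio was 0.28 (0.24 to 0.31, with an SD over regions of 0.39 and quartiles of 0.06 and 0.50). The fold was higher in SuUR at 472 regions (81.8%). At the 366 regions called in OrR, a choice that favours OrR, the median log2 ratio was 0.15 and 262 (71.6%) were higher in SuUR. Spearman's rho of the folds across the union was 0.66, and regions are not independent replicates. Of 211 regions called in SuUR alone, 180 had an OrR fold of at least 2 over the 10 kb background. More than 2-fold differences were found at 28 regions higher in SuUR and 1 higher in OrR. The largest in SuUR were at 1006401 to 1007100, with folds of 8.01 in SuUR and 2.16 in OrR, and at 7756701 to 7757500, with 4.76 and 1.28. The region higher in OrR, at 8740701 to 8741400, had folds of 3.34 in OrR and 0.814 in SuUR. Its neighbour at 8739801 to 8740600, called in SuUR alone, went the other way, with 3.78 in SuUR and 2.10 in OrR.

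The number of ORC2-enriched regions inside the domains depended on the threshold and background in SuUR, and in OrR on how low coverage was counted. In OrR 1 region lay inside and 367 outside, or 0.446 per Mb (0.0113 to 2.49) against 17.7 per Mb (15.9 to 19.6). In SuUR, where the domains held 71.8% of the region-free coverage, 5 regions lay inside and 547 outside, or 2.23 per Mb (0.725 to 5.21) against 26.4 per Mb (24.2 to 28.7). The ratio of inside to outside density was 0.0253 (0.000638 to 0.142) in OrR and 0.0847 (0.0274 to 0.199) in SuUR. None of 1000 random placements of the domains held as few regions in either library, with lowest counts of 18 in OrR and 29 in SuUR. The arm mean in the background makes regions harder to call where coverage is low. The domains were chosen by low OrR relative to SuUR density, which held down the OrR count, so the OrR placements are no independent support. The SuUR placements are not fully independent either, since 92.9% of OrR regions overlapped a SuUR region. With the local background alone 15 SuUR regions lay inside and the density ratio was 0.242 (0.135 to 0.403) at 3-fold and 0.294 (0.133 to 0.565) at 4-fold. At 2-fold it was 0.860 (0.697 to 1.05), with 105 SuUR regions inside, or 46.9 per Mb against 54.5 outside, and 0.540 (0.412 to 0.697) with unlisted bases at 4. In OrR the local background alone at 3-fold gave 101 regions inside and turned the ratio to 2.41 (1.91 to 3.002), or 2.59 (2.07 to 3.22) at full depth. With unlisted OrR bases at 4 at full depth, 7 regions lay inside and the ratio was 0.174 (0.0694 to 0.362).

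The SuUR regions inside domains, at 4660601, 15425701, 15498501, 20148101 and 21899001, had folds of 6.22, 3.71, 6.88, 7.09 and 4.87 over the larger background. All 5 lie in domains with ratios of 1.53 to 2.23. With the local background alone, 7 of the 15 SuUR regions inside domains lay in the 5 domains with ratios over 4. The OrR region inside a domain, at 15498701 to 15499500, had a fold of 4.05 and overlapped the SuUR region at 15498501 to 15499600. The SuUR regions at 4660601, 15425701, 20148101 and 21899001 were not called in OrR with the arm mean in the background. Their OrR folds over the 10 kb background were 5.31, 3.87, 6.40 and 4.83, with unlisted bases at 0. With the local background alone and unlisted bases at 4, their domains held 1, 2, 1 and 2 OrR regions at full depth.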

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

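The alternatives with unlisted bases at 2 or 4, the local background alone, each read end once (with or without equal numbers of ends) and the regions called in OrR were chosen after the data were examined; the others were planned. The number of SuUR-higher domains ranged from 8 (2-fold threshold) to 12 and their length from 1580 to 2780 kb, within 1.5 times the reported values under all 10 alternatives run. The 2-fold domains overlapped 8 of the 11, and unlisted bases at 4 in OrR and 0 in SuUR gave domains that overlapped 10. OrR-higher domains numbered 2 at 1.3-fold and 0 with unlisted bases at 4, where the ratio went from 1.49 to 1.44 and 3 of 5 windows stayed over the cut. Enriched regions numbered 820 in OrR and 995 in SuUR at 2-fold and 171 and 270 at 4-fold, by construction of the threshold, and the OrR regions shared with SuUR were 755 (92.1%) and 150 (87.7%). The density ratio inside to outside the domains in OrR was 0 with domains at 2-fold, where a count of 0 allows up to 2.33 regions per Mb, and with the local background alone it was reversed, at 2.41, or 1.95 at 2-fold, 3.35 at 4-fold and 2.59 at full depth. With the local background alone and unlisted bases at 4, at full depth, it was 0.174, or 0.389 at 2-fold. Unlisted bases at 4 and full depth with the arm mean kept gave 0.0257. With the local background the OrR value therefore depends on how unlisted bases are counted. In SuUR it was 0.242 with the local background alone, 0.860 at 2-fold and 0.294 at 4-fold, and with unlisted bases also at 4 it was 0.181, or 0.540 at 2-fold. The median log2 ratio at enriched regions, 0.28 (0.24 to 0.31), was 0.34 with the 50 kb background, 0.33 with each read end once and 0.15 at the regions called in OrR. Of all alternative values, 35 stayed within 1.5 times of the reported ones and inside any interval given, and 18 that moved and 4 that reversed are given above. A further 8, all density ratios, changed by over 1.5 times but inside the wide interval of the reported ratio: in OrR 0.0799 with domains at 1.3-fold, 0.0496 with low-density runs as domains and 0.0545 with regions at 4-fold, and in SuUR 0.134 with domains at 1.3-fold, 0.0493 with domains at 2-fold, 0.132 and 0.139 with regions at 2-fold and 4-fold, and 0.181. Causes were not tested unless named. Depth limits what is seen in OrR domains, where 59.9% of bases lie under the listing minimum.

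No paired analysis was possible because each genotype has 1 library and no test was made. Leaving out a replicate was not possible for the same reason. Collapsed duplicate positions, the strand rule and the promoter alternatives were not run. All reads were used in the reported values, so that alternative is the reported value.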

Other observations

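All tests below were chosen after the results were seen; random placement was planned with the arm mean in the background and is used here with the local background alone.

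Long stretches without ORC2-enriched regions of at least 3-fold differed widely in their SuUR/OrR ratio. Between neighbouring SuUR regions called on the local background, the 2 longest gaps, 17.60 to 17.96 Mb (359.9 kb) and 16.91 to 17.26 Mb (350.35 kb), had median log2 SuUR/OrR of 3.77 and 3.40. The domains over them hold 18 and 19 SuUR regions of at least 2-fold over the local background. The gaps at 11.53 to 11.81 Mb (279.35 kb) and 15.91 to 16.16 Mb (250 kb) had 0.68 and 3.02. The gap at 12.70 to 12.97 Mb (269.75 kb) had 0.12, although it holds the OrR low-density run at 12.81 to 12.93 Mb, with a ratio of 1.38, and that at 20.43 to 20.66 Mb (227 kb) had -0.21. In both tracks nothing was listed over 12 blocks of at least 10 kb, the longest at 21427102 to 21539441 (112.34 kb) and 15653267 to 15727445 (74.2 kb).

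Read density was lower in OrR than in SuUR across the domains. Bases under the listing minimum do not account for all of it, since the pooled ratio was still 1.85 with unlisted OrR bases at 4 and SuUR bases at 0. Fewer enriched regions over an unchanged amount of DNA would leave OrR at the level of region-free windows, but 97.7% of OrR domain windows lay below the 5th percentile of those windows, 76.9% with reference windows of any listed share, and 59.7% with unlisted bases of the domains also at 4. In SuUR 37.6% lay below the 5th percentile of its region-free windows, and 7.24% with reference windows of any listed share. The domains were chosen by the ratio of the libraries, so this test is not independent of that choice. ORC2 spread thinly stays open without an input library, so lower DNA copy number in OrR is a hypothesis, and with 1 library per genotype, genotype cannot be told apart from any other difference between the libraries.

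ORC2-enriched regions of at least 3-fold were rarer inside the domains in SuUR. The arm-mean background hid part of them, since the density ratio rose from 0.0847 to 0.242, but its upper limit of 0.403 stayed under 1. At 2-fold over the local background the ratio was 0.860 with an interval that holds 1, and 0.540 with unlisted bases at 4, so whether weaker regions are rarer inside cannot be told. Of 1000 random placements of the domains, 0 held as few regions of 3-fold. The domains were chosen from these same tracks by low OrR density relative to SuUR, and 92.9% of OrR regions overlapped a SuUR region. The placements are therefore not independent of that choice. SuUR was also thinned to 45.0% of its reads, its depth inside the domains relative to outside. This gave 28.8 regions of 3-fold per Mb outside, against 27.7 before thinning and 6.70 inside. With the arm mean in the background, 0 SuUR windows passed the fold but not the adjusted value. Calls thus rested on the fold, which thinning keeps on average, so this test cannot tell whether too few reads play a part.

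Fold over background was higher in SuUR than in OrR at enriched regions. Repeat reads do not account for all of it: at 214 regions in recovered runs the median log2 ratio was 0.28 with all reads and 0.25 with each end counted once at equal numbers of ends. Counting ends once caps high folds, and the median fold fell from 3.05 to 2.60 in OrR and from 3.63 to 3.05 in SuUR. The median was 0.28 over the union, 0.18 at regions called in both libraries and 0.15 at those called in OrR, so a union with more SuUR regions does not account for all of it, and its share was not separated. Outside the domains 11.7% of SuUR bases and 9.60% of OrR bases were unlisted and set to 0. Folds were not recomputed with these bases at 4, so the effect of the listing minimum on the ratio was not measured over the union. At the 214 regions above, at least 80% of the surrounding 10 kb was listed in both libraries. Immunoprecipitation efficiency cannot be told apart from genotype with 1 library each, and no biological explanation was tested.

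A further hypothesis was that the SuUR/OrR ratio rises with the distance between neighbouring SuUR regions of at least 3-fold. Only gaps holding at least 3 windows of 10 kb were used. Most of the 589 SuUR regions called on the local background lie closer together, and their gaps were left out. Across 213 gaps Spearman's rho between gap length and median log2 ratio was 0.318, above the highest of 1000 circular shifts of the ratio profile (0.196; one-sided permutation p = 0.001, the smallest they can give). Without the 5 gaps of at least 240 kb rho was 0.273 (p = 0.001), and from 30 to 120 kb it was 0.218 across 181 gaps. The size of the change lay mostly in those 5 gaps: the median fold was 0.924 at 30 to 60 kb, 0.957 at 60 to 120 kb and 1.05 at 120 to 240 kb, against 8.12 in the 5. Of 32 gaps of at least 120 kb, 8 had a median over 1.5-fold, so gap length alone does not set the ratio. With regions of at least 2-fold over the local background rho was 0.252 across 170 gaps (p = 0.008), and 0 gaps reached 240 kb. The relation of gap length to the ratio is a hypothesis. Gaps are not independent replicates.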
